A study of Mus musculus with 8 samples.

How the data were processed

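Total RNA of dorsal root ganglia from ovariectomized female mice (8 samples), 4 with a 17β-estradiol pellet and 4 with a placebo pellet, was made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. Per the submitters' processing notes the reads were aligned with HISAT2 2.0.5, and the builds mm10 and hg38 are both named there. The counting program, the scaling method and the annotation release are not given in the sources used here. Of the 54532 gene identifiers deposited, 99.9% are in GENCODE release M21 of the mouse (assembly GRCm38, the same as mm10), and 98.3% of those have identical coordinates, so positions are given on mm10.

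The authors deposited 1 table of 54532 genes with an FPKM value per sample, fragments scaled to gene length and to library size. No header states the unit, which was taken from the values. Multiplied by the gene length, the values of a sample are whole multiples of a single step, which is the worth of 1 read, so the reads per gene and library could be recovered. The library size inside the FPKM values differs from the sum of the recovered reads by a factor between 0.84 and 1.06 per sample, so a scaling between samples is already contained in them. Of the 201551 values above 0, all but 15 lie within 0.001 reads of a whole number, the largest deviation among them being 8.5e-05 reads. The remaining 15 values, in the 5 genes Calca, Calcb, Nmb, Nppb and Mrgprb13, lie between 0.0509 and 0.487 reads from a whole number. They were used as deposited in the main fit and set to missing in an alternative.

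Depth was 17838850, 21269575, 22200121 and 18764975 reads in placebo 1 to 4 and 22390399, 18730647, 22212757 and 18230260 reads in estradiol 1 to 4. Floors of 3 reads cover counting error only. No pair of samples within a group agreed within sampling noise (chi-square per degree of freedom 15.2 to 242), so each was counted as a sample.

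The tests had been fixed for counts, with a stated fallback for FPKM, which was used because the table holds FPKM. Genes with a mean of at least 0.5 FPKM over the 8 samples were tested (16300 genes, 29.9% of the table). log2(FPKM + 0.1) was compared between the groups with limma 3.58.1 (empirical Bayes with trend and robust settings, no covariate) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold change on this scale understates the change of low genes. Confidence intervals are 95%. Means and SDs are of FPKM, with 4 samples in each group.

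Before the data were examined 40 gene lists were fixed, covering itch molecules, classes of sensory neurons, ion channels, hormone responses, immune and stress responses, metabolism, and markers of glial cells and of tissues next to the ganglion. Each list was tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 40 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in a single direction, were run beside it. The mean deviation of a list in a sample is the mean over its members of the log2 value minus the gene's mean over the 8 samples.

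Genes were named by a rule fixed in advance. It takes genes past the threshold with a mean of at least 1 CPM and groups that do not overlap, and where fewer than 5 pass in a direction the genes of smallest p up to 5. From each list it takes the members past the threshold, at most 4, or else the 2 of smallest p. Nppb, Mrgpra3, Mrgprd, Hrh1, Il31ra, Trpv1, Trpa1, Esr1, Esr2, Gper1 and Pgr were always included. Genes named outside the rule are marked as chosen after their values were seen.

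The fit was tested on simulated data, 5 datasets with 200 changed genes each at the means and depths of these libraries (median dispersion 0.026), in which 27 of 80500 unchanged genes were called. Each gene was given the median dispersion of genes of similar level, and genes were drawn independently. Alternatives concerned the weighting (limma voom on the recovered reads, with and without sample quality weights), the scaling, the filter, the pseudocount, the threshold, gene classes, a replicate block and each sample left out in turn. After seeing the data 6 more were added, namely the 15 values set to missing, placebo 1 and placebo 2 left out, the mitochondrial genes left out, the mitochondrial share as a covariate, the first residual principal component as a covariate, and the trend on gene length removed from each sample by loess (span 0.5). The residual component is taken after the groups are fitted, so it cannot move a fold change and lowers the residual spread by construction. The mitochondrial share is made from the reads of the mitochondrial transcripts themselves. Gene recovery and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.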

Results

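RNA from mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, was sequenced from ovariectomized females. For 4 samples the mice carried a pellet releasing 17β-estradiol slowly (estradiol 1 to 4), and for the other 4 a placebo pellet (placebo 1 to 4). The labels do not say whether the samples of a group are single animals or pools, so the p-values measure the spread between these samples. The deposited values correspond to between 17838850 reads (placebo 1) and 22390399 reads (estradiol 1) per library. At these depths 3 reads on a gene of 1 kb equal between 0.131 FPKM (estradiol 3) and 0.2 FPKM (placebo 1). The question put by the study's design is whether replacing estradiol changes the transcripts of itch signalling molecules in these ganglia.

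The largest fold difference among the itch genes tested was in Nppb, which encodes the natriuretic peptide used as a transmitter by a class of itch-sensing neurons. Its level was 104 ± 71.8 FPKM with placebo and 33.0 ± 6.27 FPKM with estradiol (mean ± SD, n = 4 each), a log2 fold change of -1.36 on the log2(FPKM + 0.1) scale (95% confidence interval -2.47 to -0.26). Mrgpra3, the chloroquine receptor of pruriceptors, was 13.8 ± 0.227 FPKM with placebo and 11.4 ± 1.2 FPKM with estradiol, a log2 fold change of -0.28. It belongs to a family of closely related genes. Its values are whole reads, which argues against splitting into fractions, but how reads shared within the family were assigned is not described in the sources. In both genes all 4 placebo samples lay above all 4 estradiol samples, but adjusted over all genes tested the limma p was 0.367 for each. For Nppb this separation rests on values that are not whole reads, in placebo 3 (45.5 FPKM), placebo 4 (41.0 FPKM) and estradiol 2 (37.0 FPKM). Its placebo mean is raised by placebo 1 and placebo 2, at 185 and 142 FPKM. Htr7, a serotonin receptor, was higher with estradiol, from 3.33 ± 0.822 to 4.68 ± 0.399 FPKM (log2 fold change 0.51, limma adjusted p = 0.367). Nppb lies on chromosome 4 at 147985788 to 147987205 (plus strand) and Mrgpra3 on chromosome 7 at 47588950 to 47601372 (minus strand) of the mouse assembly mm10.

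Of 26 receptors and transmitters of itch fixed before the data were examined, 23 were expressed enough to be tested, and 0 passed over all genes or adjusted over the list alone (smallest p adjusted over the list alone 0.17). By direction 13 were higher and 10 lower with estradiol, and 3 had an unadjusted p under 0.05, Nppb, Mrgpra3 and Htr7. Mrgprd, the β-alanine receptor, was 26.1 ± 15.2 FPKM with placebo and 40.1 ± 2.45 FPKM with estradiol, with placebo 1 at 10.6 and placebo 4 at 47.0 FPKM. The interleukin 31 receptor Il31ra (8.90 ± 2.77 and 10.01 ± 1.70 FPKM), the histamine receptor Hrh1 (0.781 ± 0.188 and 0.858 ± 0.184 FPKM), and the channels Trpv1 (28.2 ± 7.73 and 33.2 ± 4.41 FPKM) and Trpa1 (18.9 ± 4.93 and 15.9 ± 0.793 FPKM) overlapped between the groups, given as placebo and estradiol. The list median was 0.12 and its mean 0.02. Without placebo 4, 6 members passed when adjusted over the list alone and 0 over all genes. The same counts were 6 and 0 with the first residual component as a covariate, an alternative chosen after seeing the data. That component is taken after the groups are fitted, so it lowers the residual spread without moving any fold change. Smaller p-values are therefore favoured by construction.

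**Figure D1:**
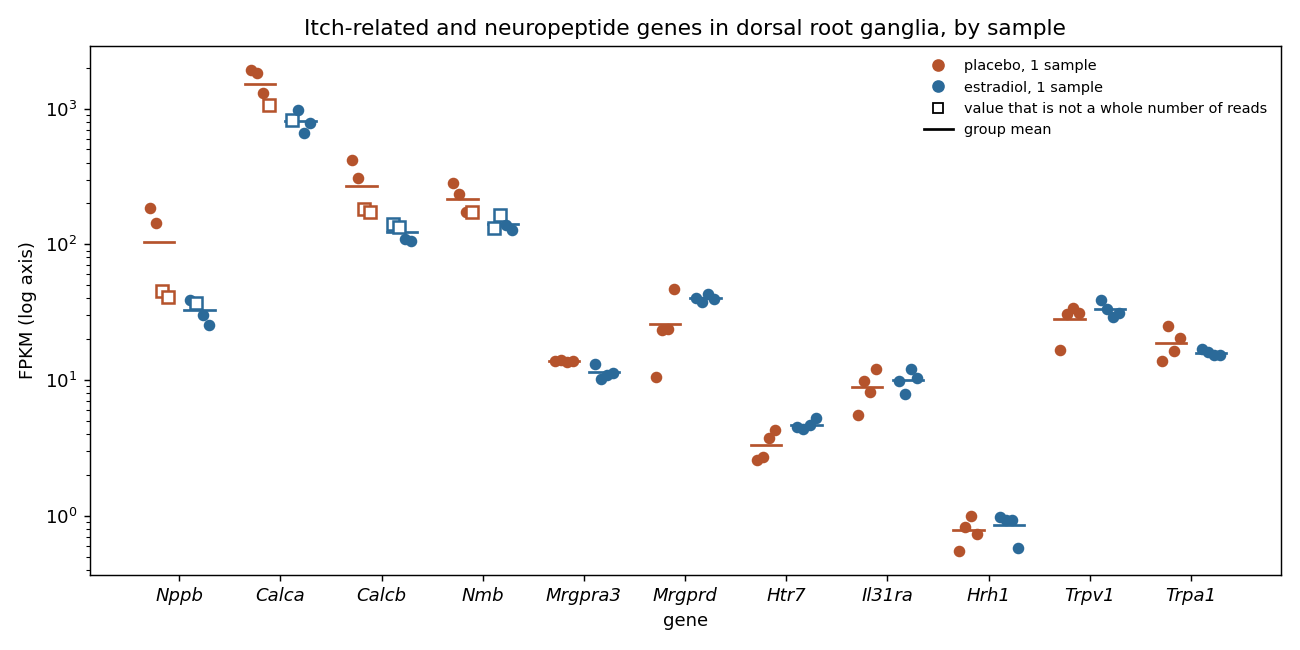
Each point is the FPKM of 1 sample for 11 genes on a log axis, placebo on the left and estradiol on the right of each gene, with a line at the group mean. Open squares mark values that are not whole numbers of reads, 12 of which are in Nppb, Calca, Calcb and Nmb.

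Calca, Calcb and Nmb, which encode neuropeptides of sensory neurons, had lower means with estradiol, and none of the 3 passed the test over all genes. Calca, which encodes the peptide CGRP, was 1523 ± 407 FPKM with placebo and 810 ± 130 FPKM with estradiol (log2 fold change -0.89, SE 0.25). Calcb, the gene of the second CGRP form, was 270.0 ± 116 and 122 ± 17.7 FPKM (log2 fold change -1.06, SE 0.29), and Nmb, the gene of neuromedin B, 216 ± 52.9 and 141 ± 16.2 FPKM (log2 fold change -0.59, SE 0.20). The limma adjusted p over all genes was 0.367 for each. Nmb was chosen after its values were seen. The list of peptidergic neuron markers, which holds Calca and Calcb and not Nmb, was not called as a group, with 6 of its 13 tested members higher and 7 lower (median -0.29, camera adjusted p = 0.23). Of these 13 genes 0 passed over all genes, and 5 passed adjusted over the list alone (smallest p 0.034). Calca, Calcb, Fam19a1 and Smr2 were lower and the receptor tyrosine kinase gene Kit was higher with estradiol, the last 3 being named after their values were seen. Calca and Calcb had the smallest p of the list and hold values that are not whole reads. The adjustment takes all members together, so the adjusted p of the other members depends on theirs.

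These levels carry a limit in the deposited values themselves. In Nppb, Calca, Calcb and Nmb 12 of the values are not whole numbers of reads, although values elsewhere in the table are, and 3 more occur in the pseudogene Mrgprb13. For Nppb they are the values of placebo 3, placebo 4 and estradiol 2, next to the boundary between the groups. With the 15 values set to missing, an alternative chosen after seeing the data, the log2 fold changes were -2.38 (Nppb), -1.05 (Calca), -1.74 (Calcb) and -0.75 (Nmb), with limma adjusted p of 0.37 for each, and with 2 placebo values left, placebo 1 and placebo 2, for Nppb and Calcb. Without placebo 1 and placebo 2 they were -0.41, -0.55, -0.55 and -0.30 in the same order, and for Nppb and Calcb both placebo values then left are among the values that are not whole reads. A reconstruction of the table, made after seeing the data, put whole-read counterparts in place of 8 of the 15 values and left the other 7 missing. The groups then overlapped in Nppb, Calcb and Nmb and stayed apart in Calca and Mrgprb13, the latter with 3 placebo and 2 estradiol values left. In Nppb and Nmb the counterparts are values listed under samples of the other group, so the overlap there follows from the exchange.

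Across the 16300 genes tested, 1 passed the limma test at an adjusted p under 0.05. That gene is Gm24776, a predicted small nuclear RNA of 86 bases on chromosome 5 at 72971179 to 72971264 (minus strand), chosen here after its values were seen. It had 4, 8, 4 and 3 reads in placebo 1 to 4 and 0 in every estradiol library (limma adjusted p = 0.00808). Against a floor of 3 reads over the 4 estradiol libraries together it was at least 6.85-fold lower with estradiol. It rests on 19 reads in all and no longer passed without placebo 1, placebo 2 or placebo 3, with a pseudocount of 1, with limma voom on the recovered reads or with the replicate block, each of which left 0 genes. The count was also 0 without placebo 1 and placebo 2, with the mitochondrial share as a covariate and with the length trend removed, all chosen after seeing the data, and with sample quality weights Olfr920 passed in its place. Filters on CPM or on protein-coding genes likewise left 0 genes. At an unadjusted p under 0.05 there were 2158 genes, 947 higher and 1211 lower with estradiol, where chance alone gives 815. That count was 1674, 941, 2852 and 4165 without placebo 1 to 4 in turn and 1375, 1389, 952 and 1252 without estradiol 1 to 4 in turn. It was 878 without placebo 1 and placebo 2 (470 higher and 408 lower) and 926 with the mitochondrial share as a covariate (520 and 406). With scaling by total reads only it was 2079, with 1079 higher and 1000 lower. With the first residual component as a covariate it was 4832, with 2426 higher and 2406 lower, a larger count that this covariate favours by construction. In these 4 fits the higher genes were thus the more numerous.

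The named genes with the smallest p in each direction had an adjusted p of 0.367 in the limma fit, and in each of them the groups did not overlap. Higher with estradiol were Cyb561a3 (3.41 ± 0.401 to 5.44 ± 0.360 FPKM, log2 fold change 0.67), which encodes a lysosomal cytochrome b561, and Fbln2 (10.8 ± 1.00 to 15.5 ± 1.06 FPKM, 0.52), an extracellular matrix protein. The same held for the farnesyltransferase subunit Fntb (log2 fold change 0.48), Rflna (0.68) and the mitochondrial carrier Slc25a29 (0.55). Lower with estradiol were the olfactory receptor gene Olfr920 (2.65 ± 0.682 to 1.04 ± 0.167 FPKM, log2 fold change -1.24) and Hmgb2 (5.04 ± 1.35 to 2.25 ± 0.322 FPKM, -1.10), a chromatin protein of proliferating cells. Srp54c (log2 fold change -0.58), Phf20l1 (-0.57) and Prg2 (-2.86) were also lower, the last encoding the major basic protein of eosinophil granules. Prg2 rests on few reads, 33, 56, 101 and 8 in placebo 1 to 4 and 3, 6, 4 and 3 in estradiol 1 to 4. Its estradiol values are thus near the floor of 3 reads, and placebo 4 is close to them. Among all tested genes the placebo samples were all above the estradiol samples in 3.93% and all below in 4.88%, where chance gives 1.43% in each direction.

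Genes of protein synthesis and respiration were called lower with estradiol as groups at the preset correlation of 0.01, and not with an estimated correlation. The correlation estimated between members was 0.94 for ribosomal protein genes, 0.94 for mitochondrial transcripts and 0.75 for nuclear oxidative phosphorylation genes. All 52 ribosomal protein genes had a negative log2 fold change (median -0.76, camera adjusted p = 3.9e-12 with a preset correlation of 0.01, adjusted p = 0.85 with an estimated correlation), and 0 of them passed singly. Rpl30 was 145 ± 106 FPKM with placebo and 51.02 ± 6.41 FPKM with estradiol, and Rps27 320 ± 262 and 98.8 ± 61.0 FPKM. All 13 transcripts encoded by the mitochondrial genome were lower (median -1.03, camera adjusted p = 7.2e-05, adjusted p = 0.85 with an estimated correlation), mt-Nd1 at 8944 ± 6417 and 3395 ± 695 FPKM and mt-Nd5 at 1943 ± 1280 and 860 ± 136 FPKM. Of 35 nuclear genes of oxidative phosphorylation 30 were lower (median -0.57, camera adjusted p = 0.00014, adjusted p = 0.85 with an estimated correlation), among them Uqcrb and Ndufa5. Placebo 3 and placebo 4 lay within the range of the estradiol libraries in all 3 lists. Placebo 1 and placebo 2 were the highest libraries in all 3 lists, and reads of ribosomal protein genes can be shared with their pseudogenes. Mitochondrial transcripts took 12.5% and 7.29% of their reads, against 2.63% to 4.10% in the other 6 libraries. Across genes, the rank correlation of gene length with the deviation of the sample was -0.40 in placebo 1 and -0.13 in placebo 2, against -0.08 to 0.27 in the other 6. Without these 2 libraries the medians were -0.14 for ribosomal proteins (camera adjusted p = 0.003), -0.18 for mitochondrial transcripts (0.12) and -0.08 for oxidative phosphorylation (0.42). The mitochondrial share as a covariate was chosen after seeing the data. With it the medians turned positive for ribosomal proteins, 0.10 (camera adjusted p = 0.006), and for oxidative phosphorylation, 0.18 (0.00014). That of mitochondrial transcripts was 0.08 (0.35), near 0 by construction, since the covariate is made from their own reads.

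Voltage-gated potassium channel genes and the markers of A-fibre and NP1 neurons were called higher with estradiol as groups at the preset correlation alone. The correlations estimated between their members were 0.71, 0.27 and 0.71 in this order. All 19 tested voltage-gated potassium channel genes had a positive log2 fold change (median 0.40, camera adjusted p = 0.00013, adjusted p = 0.85 with an estimated correlation). Kcns1, a modulatory subunit, was 15.4 ± 5.81 FPKM with placebo and 26.7 ± 1.54 FPKM with estradiol, and Kcnh1 4.58 ± 1.71 and 7.16 ± 1.12 FPKM. Of 16 markers of large-diameter A-fibre neurons 13 were higher (median 0.45, camera adjusted p = 0.0033, adjusted p = 0.85 with an estimated correlation), among them the neurofilament gene Nefh at 244 ± 68.2 and 370.1 ± 18.6 FPKM. Of 11 markers of non-peptidergic NP1 neurons 10 were higher (median 0.49, camera adjusted p = 0.027, adjusted p = 0.85 with an estimated correlation), with Prkcq at 7.75 ± 2.46 and 10.3 ± 0.986 FPKM. In none of the 3 lists did a member pass singly, over all genes or adjusted over the list alone. Placebo 1 was the lowest library in each list, and without placebo 1 and placebo 2 the medians were 0.03, 0.11 and 0.04 (camera adjusted p = 0.61, 0.12 and 0.61). With the mitochondrial share as a covariate the medians were -0.10, 0.06 and -0.12 (camera adjusted p = 0.15, 0.67 and 0.26), so that potassium channels and NP1 markers turned lower. The NP1 list also lost its call without placebo 1 (camera adjusted p = 0.24), placebo 3 (0.11) or estradiol 1 (0.061), and with scaling by total reads only (0.069).

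Macrophage markers, neutrophil and bone marrow markers, interferon-stimulated genes and nerve-injury response genes were called lower with estradiol as groups at the preset correlation alone. The correlations estimated between their members were 0.77, 0.72, 0.2 and 0.48 in this order. The lists of inflammatory mediators, MHC class II, T and B cells and mast cells were not called. Of 18 macrophage markers 17 were lower (median -0.47, camera adjusted p = 0.0031, adjusted p = 0.85 with an estimated correlation), with the adaptor gene Tyrobp at 19.7 ± 10.4 FPKM with placebo and 9.23 ± 3.51 FPKM with estradiol. All 13 tested neutrophil and bone marrow markers were lower (median -1.45, camera adjusted p = 0.0042, adjusted p = 0.85 with an estimated correlation), Lcn2 at 7.69 ± 4.47 and 2.42 ± 0.638 FPKM and Ltf at 4.68 ± 3.37 and 1.34 ± 0.445 FPKM. Their mean deviation was 0.56, 1.85 and 1.91 in placebo 1, 2 and 3 and -1.84 in placebo 4. Erythroid genes, a list not called (camera adjusted p = 0.34), had 0.66, 0.40, 1.18 and -1.37 in placebo 1 to 4 and -0.88 to 0.95 in the estradiol libraries. Of 18 interferon-stimulated genes 15 were lower (median -0.19, camera adjusted p = 0.027, adjusted p = 0.85 with an estimated correlation). Ifit1 (30.7 ± 17.5 and 9.46 ± 1.66 FPKM) and Ifit2 (13.8 ± 4.12 and 8.21 ± 0.0341 FPKM), antiviral proteins, passed adjusted over the list alone (smallest p 0.038) and not over all genes. Of 16 nerve-injury response genes 11 were lower (median -0.62, camera adjusted p = 0.047, adjusted p = 0.85 with an estimated correlation), with the neuropeptide gene Gal at 59.5 ± 28.2 and 20.1 ± 5.97 FPKM and Sprr1a at 22.8 ± 3.65 and 8.53 ± 7.44 FPKM. Without placebo 1 and placebo 2 the medians of these 4 lists were -0.04, -0.69, -0.15 and -0.23 (camera adjusted p = 0.61, 0.12, 0.054 and 0.12), and with the mitochondrial share as a covariate none of the 4 was called (0.71, 0.15, 0.15 and 0.072). The nerve-injury list also lost its call without placebo 2 (camera adjusted p = 0.22), placebo 3 (0.33), estradiol 2 (0.18) or estradiol 3 (0.13), with the length trend removed (0.066), and with the first residual component as a covariate (0.18). The interferon list lost it without placebo 2 (0.097), placebo 3 (0.11) or estradiol 4 (0.063) and with that component (0.051), the neutrophil list without placebo 3 (0.12), and the macrophage list with sample quality weights (0.069).

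**Figure D2:**
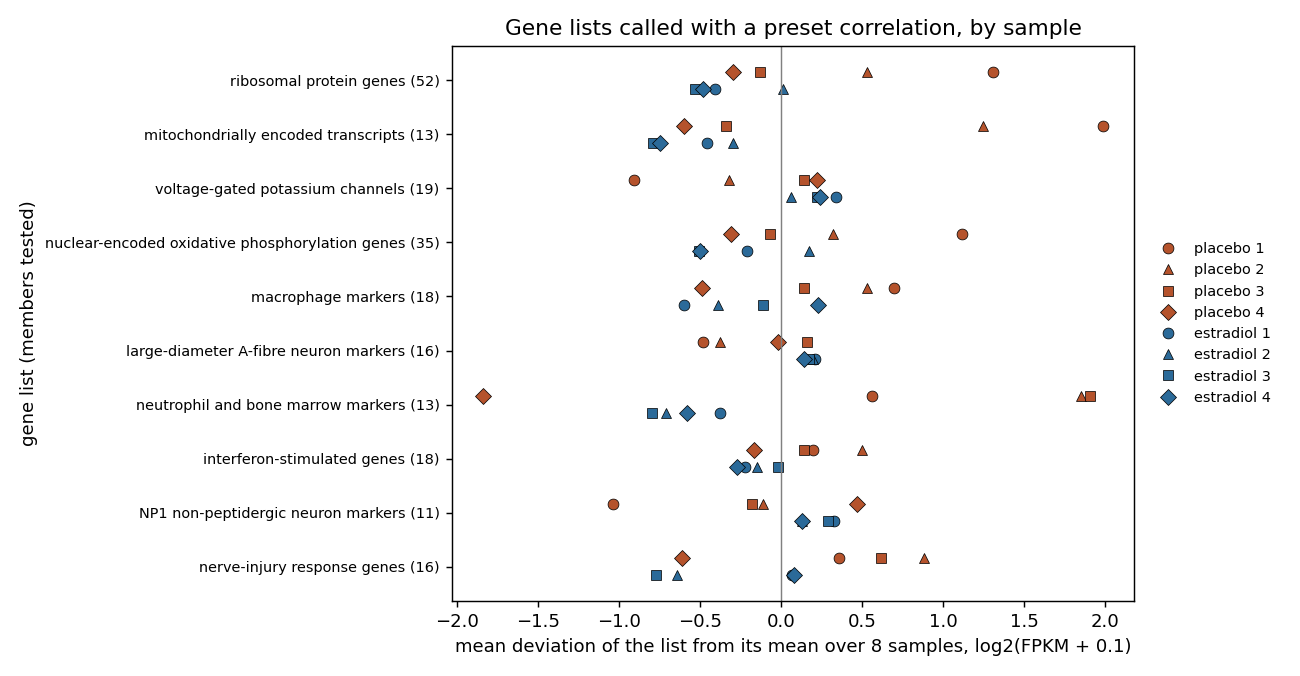
Each point is the mean deviation of a gene list in 1 sample from its mean over the 8 samples on the log2(FPKM + 0.1) scale, for the 10 lists called with a preset correlation. Placebo 1 reaches 1.31 for ribosomal protein genes and 1.99 for mitochondrial transcripts, while the estradiol samples lie between -0.53 and 0.01 and between -0.79 and -0.30.

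Among receptors of estrogen and their textbook targets no tested gene passed. Esr1 was 0.425 ± 0.0895 FPKM with placebo and 0.464 ± 0.0830 FPKM with estradiol, and Esr2 0.0847 ± 0.0353 and 0.102 ± 0.0322 FPKM. Both were under the FPKM level required and so were not tested, although Esr1, of 13661 bases, had 71 to 173 reads per library. Gper1, a membrane estrogen receptor gene, was 0.668 ± 0.329 and 1.18 ± 0.420 FPKM (limma adjusted p = 0.37), and Pgr, the progesterone receptor gene, 0.599 ± 0.239 and 0.841 ± 0.190 FPKM (limma adjusted p = 0.439). Of 18 tested members of the estrogen list 9 were higher and 9 lower (median 0.02, camera adjusted p = 0.60), and 0 passed over all genes or adjusted over the list alone.

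In all, 10 of the 40 gene lists were called with the preset correlation, and 0 with an estimated correlation or by the rotation test fry, whose adjusted p was 0.73 or 0.81 for these 10. The other 30 lists had a camera adjusted p between 0.061 and 0.92. Adding known changes to simulated data of the same depth, the limma test found 13.7%, 66% and 88.2% of genes changed 1.5-fold, 2-fold and 4-fold. Each simulated gene had the median dispersion of genes of similar level, without the shifts shared across genes in placebo 1 and placebo 2. These shares are therefore likely too high for genes of wider spread, such as Nppb (SE 0.487 in the main fit) or Rpl30 (SE 0.457).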

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

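The tests weighed here were chosen after the results were seen. In groups of 4 samples, a sample was singled out when its gap to the nearest of the others divided by the group's range exceeded Dixon's 95% critical value, which chance alone gives in about 1 in 20 groups. Of 282 groups tested 18 were singled out, where chance gives 14.1, so their number is not itself a finding.

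In the placebo group, Olfr920 was 1.62 FPKM in placebo 1 against 2.93 to 3.02 in the others, and Trpv1 was 16.8 FPKM in placebo 1 against 30.9 to 33.8. Gal was 17.9 FPKM in placebo 4 against 68.0 to 80.9, and Sgk1 was 11.3 FPKM in placebo 4 against 6.14 to 6.51. Mrgprb13 was 0.317 FPKM in placebo 2 against 0.0877 to 0.104, Xist was 0.562 FPKM in placebo 2 against 16.5 to 29.7, and the mast cell list had a mean deviation of 1.27 in placebo 2 against -0.53 to -0.27.

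In the estradiol group, the adipocyte list had a mean deviation of 3.61 in estradiol 3 against -1 to -0.33, with Pck1 at 68.4 FPKM against 0.968 to 1.49 and Lipe at 16.1 FPKM against 2.35 to 2.85. The cell-cycle list had a mean deviation of -0.27 in estradiol 3 against -0.03 to 0. The estrogen list had -0.21 in estradiol 1 against 0.09 to 0.12, and 2 genes of other lists stood apart in the same library, the clock gene Nr1d2 at 12.4 FPKM against 13.6 to 13.8 and the mural cell marker Myh11 at 1.66 FPKM against 3.07 to 3.28. Slc25a29 was 6.09 FPKM in estradiol 2 against 5.11 to 5.25, and Cdh19 15.2 FPKM in estradiol 2 against 16.8 to 17.1. Tyrobp was 14.5 FPKM in estradiol 4 against 7.39 to 7.58, and Hrh1 0.584 FPKM in estradiol 4 against 0.932 to 0.977.

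Ribosomal protein transcripts stood apart in placebo 1 and placebo 2, with mean deviations of 1.31 and 0.53 against -0.53 to 0.01 in the other 6 libraries. A bias by the deposited gene length does not account for the whole of it, because with that trend removed the deviations were still 1.08 and 0.48, against -0.03 at most elsewhere. The deposited length, 3020 bases for Rpl30, can differ from that of the transcripts present, so a bias by transcript length is not bounded by this. Mitochondrial reads taking a share of the reads would lower other genes in these libraries before scaling, whereas ribosomal protein genes were higher there. The deposited values already contain a scaling, with a factor of 0.84 in placebo 1 and 0.905 in placebo 2. Such a lowering need therefore not appear in them, and the direction alone decides nothing. With the mitochondrial genes left out and scaling by the other reads, the median log2 fold change of the list was -0.72, against -0.76 in the main fit. The median of all genes moved from 0.006 to 0.045 with that scaling, so the difference cannot be separated from the scaling. The placebo treatment itself cannot be told apart from a difference of these 2 libraries in handling or RNA quality, since 2 of the 4 placebo libraries lay above the highest estradiol library and the labels record no quality measure. Other values set the same 2 libraries apart, a mitochondrial share of 12.5% and 7.29% against at most 4.10%, a rank correlation with gene length of -0.40 and -0.13 against at least -0.08, and mitochondrial ribosomal RNA at 0.389% and 0.246% of reads against at most 0.12%, while nuclear ribosomal RNA was 0.001% in every library.

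Xist, the RNA that coats the inactive X chromosome, was nearly absent in placebo 2 (194 reads), at 3.4% of the median of the other libraries. Male tissue is argued against by the Y-linked genes, with 2 reads in that library, and loss of long transcripts by genes over 10 kb, whose median deviation there was -0.02 while that of Xist was -4.22. A single X chromosome in part or all of the cells may account for it but stays open, as the 5 genes that escape inactivation went both ways (median log2 ratio -0.18, with Kdm5c at -0.68, Eif2s3x at -0.40 and Ddx3x at 0.26). The 538 tested X-linked genes had a median deviation of 0.138 in placebo 2 against -0.045 to 0.037 in the other libraries. This median cannot decide it, since most X-linked genes are expressed from the active X alone in either case. Autosomes 3 and 13 also reached 0.12 and 0.123 in the same library. No biological explanation named by the design was tested.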

How the results depend on the processing

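The 6 alternatives that set the 15 values to missing, left out placebo 1 and placebo 2, left out the mitochondrial genes, used a covariate (2 of them) or removed the length trend were chosen after seeing the data. The count of changed genes was 1 in the main fit. It was 0 with limma voom on the recovered reads, with CPM of at least 1 in at least 4 samples, with protein-coding genes only, with a pseudocount of 1, without placebo 1 and placebo 2, with the mitochondrial share as a covariate and with the length trend removed, and 4 with the first residual component as a covariate. Leaving out each sample in turn gave 0 to 2 genes, 0 without placebo 1, placebo 2 or placebo 3 and 2 without estradiol 1 or estradiol 3. It was 1 with quality weights (Olfr920 in place of Gm24776), and Gm24776 alone under the 3 other scalings, with no filter, at a fold of 1.2, at an adjusted p under 0.1, with mitochondrial genes left out, alone or together with tissue-list genes, and with the 15 values missing. Scaling by total reads only moved the median of all genes to 0.099. The count of itch list members that passed over all genes was 0 in every alternative run. Adjusted over the list alone it was 6 without placebo 4, 6 with the first residual component, 1 with the 15 values missing and 0 in the others. The member that passed with the 15 values missing was Nppb, for which placebo 1 and placebo 2 were then the only placebo values left. The residual component was taken after the groups were fitted, so it favours smaller p-values by construction, here and for the 4 genes. Of the 10 lists called, 0 remained with an estimated correlation and 0 with fry. The count was 16 with quality weights and with no filter, 4 without placebo 1 and placebo 2 (1 of the 10 kept, ribosomal proteins), and 7 to 17 when each sample was left out, 7 without placebo 3 and 17 without placebo 4. With the mitochondrial share as a covariate 7 were called, 2 of them among the 10, ribosomal proteins and oxidative phosphorylation, both turned to higher. NP1 markers (median -0.12) and potassium channels (-0.10) also turned, without a call, and the cause of these turns was not tested. The median of mitochondrial transcripts was 0.08, near 0 by construction, since the covariate is made from their own reads.

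Replicate numbers do not pair the samples, as the correlations of same-numbered samples were -0.13, -0.32, 0.06 and 0.11 and 2 of the 8 samples, placebo 3 and estradiol 4, correlated best with their own number. The replicate block gave 0 genes and 13 lists, among which the nerve-injury list was not (camera adjusted p = 0.054). The planned tests DESeq2, edgeR and the surrogate variable of sva were not run, as the deposited unit is FPKM; limma voom on the recovered reads and the residual component took their place.

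Of 2436 log2 fold changes of named genes under alternatives, 25 changed sign, none in a gene that passed the test, and the cause was not tested. With the mitochondrial share as a covariate these were Mrgprd -0.007, Th -0.01, Cacng2 -0.006, Trpm2 -0.014, Oprd1 -0.212, H2-Aa 0.124, H2-Eb1 0.236, mt-Nd1 0.003, Pmp2 0.065, Ighm 0.005, Hbb-bt 0.056, Aspa 0.08, Hrh1 -0.031, Il31ra -0.237 and Trpv1 -0.1. The reads of mt-Nd1 are part of that covariate, so its value near 0 follows from the construction. Without placebo 1 and placebo 2 the values that changed sign were Oprd1 -0.134, H2-Aa 0.027, H2-Eb1 0.145, Hrh1 -0.028 and Il31ra -0.006. Quality weights gave Hrh1 -0.11 and Trpv1 -0.004. Leaving out each sample in turn gave Hrh1 -0.011 (without placebo 1) to 0.277, Il31ra -0.001 (without placebo 1) to 0.372, and Ighm -0.199 to 0.044 (without estradiol 3).

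A chance split of the samples could not be excluded for the counts of genes and of lists. Of the 35 splits of the 8 samples into 4 and 4, 6 gave at least the 1 gene called (highest other 1) and 24 at least the 10 lists (highest other 26). For the 0 itch genes the splits decide nothing, since all 35 necessarily give at least 0 (highest other 0). For genes at an unadjusted p under 0.05, 2 splits gave at least the 2158 observed, the other being placebo 1, 2 and 3 with estradiol 2 against the rest (3229), which points to a structure of the samples.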

Other observations

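The tests in this part were chosen after the results were seen. Among lists that were not called, 14 of 17 calcium channel genes were higher with estradiol (median 0.28, camera adjusted p = 0.064) and 8 of 10 sodium channel genes (median 0.39, 0.093), with Scn4b at 55.5 ± 20.7 FPKM with placebo and 81.6 ± 3.65 FPKM with estradiol. Other neuron lists had medians of 0.29 (cold and C-LTMR neurons, with the menthol receptor gene Trpm8 at 5.08 ± 1.90 and 7.59 ± 0.577 FPKM), -0.29 (peptidergic neurons), -0.17 (NP2 pruriceptors), 0.03 with a mean of -0.33 (NP3 pruriceptors), 0.07 (TRP channels) and -0.07 with a mean of 0.09 (opioid system). Inflammatory mediators had 5 of 6 tested members lower (median -0.60, camera adjusted p = 0.16), Cxcl10 at 1.22 ± 0.260 and 0.628 ± 0.205 FPKM. Medians of the response lists were 0.19 (glucocorticoid-responsive genes), -0.19 (MHC class II), 0.09 (immediate-early genes), -0.10 (heat-shock and ER-stress genes), 0.03 (clock genes), 0.09 (cholesterol synthesis) and -0.20 (cell cycle). Egr2 was the 1 immediate-early gene that passed adjusted over the list alone (4.85 ± 0.693 and 7.57 ± 1.22 FPKM). It is also in the list of myelinating Schwann cell markers, where 0 members passed (smallest limma p adjusted over the list alone 0.054).

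Markers of tissues next to the ganglion varied widely within groups. Skeletal muscle markers had a mean deviation of -5.32 in estradiol 1 and 3.44 in estradiol 2, with Tnni2 at 0.539 and 585 FPKM, and 2.40 in placebo 1 and -2.60 in placebo 2. Spinal cord and central glia markers had 1.81 in estradiol 4 and -1.46 in estradiol 1, with Mog at 8.27 and 0.263 FPKM. List medians were -1.38 for muscle, 0.65 for adipocytes, 0.38 for spinal cord, 0.69 for bone and cartilage, -0.37 for erythroid genes, -0.10 for T and B cells and 0.03 with a mean of -0.09 for mast cells. They were 0.26 for endothelium, 0.21 with a mean of -0.02 for mural cells, 0.30 for fibroblasts, 0.05 for satellite glia and -0.16 for myelinating Schwann cells. Their camera adjusted p lay between 0.061 and 0.92.

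The 15 values in 5 genes that are not whole reads deviate by at least 0.0509 reads, far above the 8.5e-05 reads of all other values, which argues against rounding or number format. For Mrgprb13, fractional counting of shared reads is argued against by 27 other expressed genes of the Mrgpr family, whose 166 values above 0 deviate by at most 4.8e-07 reads. Calca, Calcb, Nmb and Nppb are outside that family, so it does not speak for them. For these genes the only comparison is with the rest of the table, where no value deviates by more than 8.5e-05 reads. Of the 15 values, 5 are a whole number of reads on the scale of another sample, where chance gives 0.009, although that sample lists a different value for the gene. Another 5 become whole after a whole number of FPKM is added to or taken from the sample's own value, where chance gives 0.617, and 1 more is whole on the scale of another sample after such a shift (chance 0.23), which leaves 4 unmatched. How these values arose is not known from the files.

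The matches are specific. The Calca value listed for placebo 4 (1068 FPKM) equals 40110 reads on the scale of estradiol 1, whose own listed value (821 FPKM) lies exactly 247 FPKM lower. On the same kind of scale, for Nppb placebo 3 lists a value equal to 647 reads of estradiol 2, and estradiol 2 lists a value equal to 566 reads of placebo 4, whose own listed value is exactly 4 FPKM higher. For Nmb, the value of placebo 4 is worth 3078 reads of estradiol 1 and that of estradiol 2 is worth 2547 reads of placebo 4. For Calcb the shifts are 22 FPKM in estradiol 1, 20 FPKM in estradiol 2 and -26 FPKM in placebo 3, and placebo 4 matches estradiol 1 after a shift of -10 FPKM.

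Read in this way, 8 of the 15 values have a whole-read counterpart, and the other 7 have none. All 3 placebo values among them are listed higher than that counterpart, and all 5 estradiol values lower. As listed, the 4 placebo samples lie above the 4 estradiol samples in all 5 genes. For 5 of the 8 the counterpart is a value listed under a sample of the other group, so their direction follows from the exchange. The same holds for the overlap in Nppb and Nmb. Only the whole-number shifts could have gone either way, those of Calcb and 2 others that match a counterpart among these 5. With the counterparts used and the rest missing, the groups overlap in Nppb (lowest placebo 37.0, highest estradiol 45.5 FPKM), Calcb (156 and 163 FPKM) and Nmb (164 and 174 FPKM) and stay apart in Calca (1295 and 1068 FPKM) and Mrgprb13 (0.09 and 0 FPKM, with 3 placebo and 2 estradiol values left). The log2 differences were then -1.53, -1.06, -0.51, -0.95 and -1.34. This reconstruction is a hypothesis about the table and entered no other test.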
